A study of Mus musculus with 10 samples.

How the data were processed

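Per the labels' protocols, EML-C1 cells were cultured untreated or with 10 ng/ml EPO, with 10 ng/ml IL-3 and 10 µM all-trans retinoic acid to which 10 ng/ml GM-CSF was added after day 3, or with both sets of factors. Total RNA was extracted from sorted subpopulations and labelled with Cy3 by the 1-colour Low Input Quick Amp method, per the labels' protocols. Spot intensities were deposited as Agilent Feature Extraction 11.0.1.1 output, and per the file headers the processed intensity of each spot came from the extraction protocol GE1_1100_Jul11. The deposited series matrix held the same processed intensities in 62969 rows. Its column medians were 30.8 for untreated cells, 17.0, 29.9 and 20.5 for EPO Sca1-low, Sca1-high and day 6, 33.2, 30.0 and 28.8 for IL-3/GM-CSF and 36.9, 35.9 and 26.7 for the combined treatment. These are intensities and not counts, and no reads or scan images were used here.

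All 10 arrays were kept. The quality summary of the extraction software read ExtractionEvaluate for both day 3 arrays of EPO and of the combined treatment and for IL-3/GM-CSF Sca1-low. It read ExtractionInRange for the other arrays. Of 62976 spots per array 59305 were not controls, and these held 55681 probes, of which 399 were repeated 10 times. Spots that the extraction software marked as non-uniform or as population outliers were set to missing. The log2 processed signal was taken relative to the 75th percentile of its array, and repeat spots were averaged. The SD of repeat spots lay between 0.04 and 0.09 log2. A RefSeq table paired accessions with symbols and named 27235 probes, and 98.1% of the probes carrying an NM or NR accession were matched. The 28446 probes without a name were left out of the gene tests, and 16194 of them cover mm9 regions. For the 5476 symbols with several probes the brightest probe was kept, which left 20508 of 20660 symbols without missing values. Genes well above background on at least 2 arrays were tested, 14223 in all. Of 54 named genes with several probes, 8 had a lowest correlation between probes under 0.5, namely Clec1b, Cdk1, Oas1a, Klra7, Tcp11l1, Asb18, Ikzf4 and Zfp11, with -0.279 for Zfp11 as the lowest.

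With 1 array per condition, genes were tested in limma 3.58.1 (R 4.3.3) with an additive model of untreated mean, 3 treatment means and 2 population offsets. Its 4 residual degrees of freedom hold the treatment-by-population interaction, so its p-values take that spread as error. Every p was adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The adjusted p was also taken over the members of each list alone. A fit of the 6 day 3 arrays was planned beside it. Treatments were compared with each other and with the untreated array, Sca1-low with Sca1-high cells, and day 6 with day 3. The comparisons with untreated cells share 1 control array and are not independent. Single arrays were compared by counts of genes at least 2-fold apart and well above background on the higher side. Where no array of the lower side was well above background, the difference is a lower bound against the background limit, and means over arrays of which only some were well above background are given with their number.

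The 18 gene lists were written before the data were examined. They cover stem and progenitor (22 of 24 measured), erythroid (27 of 32), haemoglobin (8 of 11), haem (20 of 20), myeloid (19 of 20), neutrophil (29 of 34), monocyte (22 of 30), mast cell (17 of 18), eosinophil (8 of 11), megakaryocyte (19 of 20), B lymphoid (10 of 15), T and NK (10 of 14), retinoic acid (12 of 19), STAT5 (15 of 18), proliferation (25 of 26), interferon (14 of 20), stress and p53 (16 of 18) and housekeeping genes (11 of 13). Lists were tested with camera at a preset correlation of 0.01, with adjustment over the 18 lists of a comparison and an estimated correlation as the check. Random lists matched on mean expression in 20 bins were drawn 10000 times with seed 1.

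Genes were named by a rule written before the data were examined. Per comparison, it took the 6 highest and 6 lowest genes with 1 sign in all 3 treatment or population blocks, called genes first and then by bounded change, without clone-type symbols. It also took the 4 members of each list with the largest difference, and the 4 highest and 4 lowest genes of each difference between single arrays. The 8 marker genes of the marker plot and Gata1 and Epor were chosen after their values were seen. The position of an array was the median over genes of its distance from IL-3/GM-CSF day 6, divided by the distance of EPO day 6. A shift of 0.1 counted as a move, which is a stated choice, since without replicates no spread could be computed.

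Alternatives planned before the data were examined were background correction by normexp with an offset of 50 and quantile normalization, quantile normalization alone, the series matrix values, no filter on dim probes, a filter on all 10 arrays, the mean of all probes of a gene, slide as a block, an intensity trend, a threshold of 2 on the log2 scale, an estimated correlation, each array left out in turn, day 3 arrays only and only the groups compared. The planned normexp step named mean spot signals, which the files do not hold, and the median spot signal was used in its place. Chosen after seeing the data were the analyses without the 2 dimmest arrays and with only slide 2, the lists with slide as a block under either correlation, and the mixture shares under other normalizations and from genes chosen on other arrays than the 2 ends. The slides held untreated, EPO day 6 and combined day 6 (slide 1), the day 3 arrays of EPO and IL-3/GM-CSF (slide 2), and the day 3 arrays of the combined treatment with IL-3/GM-CSF day 6 (slide 3).

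The model was tested on simulated data with 200 of 14223 genes changed. Each simulated change was equal in all populations or treatments and lay on independent noise, while real differences varied between them. The shares recovered are therefore not the power of the real tests. Changes of 2, 4 and 8 log2 units were recovered for 46.3%, 88.1% and 100% of genes in EPO against IL-3/GM-CSF with 10 false calls, for 49.3%, 83.6% and 95.5% in the combined treatment against EPO with 7, and for 58.2%, 82.1% and 97.0% against IL-3/GM-CSF with 4. For the Sca1 fractions the shares were 40.3%, 85.1% and 97.0% with 3 false calls in 10 arrays, and 46.3%, 86.6% and 100% with 5 in 6 arrays. For day 6 against day 3 they were 68.7%, 92.5% and 100% with 16 false calls. Against untreated cells they were 14.9%, 73.1% and 90.9% for EPO with 4 false calls, 13.4%, 59.7% and 93.9% for IL-3/GM-CSF with 4, and 17.9%, 73.1% and 93.9% for the combined treatment with 10. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.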

Results

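Gene expression was measured on 1-colour 60-mer arrays in EML-C1 cells, a mouse blood progenitor line that can form erythroid and myeloid cells. Untreated cells at day 0 gave 1 array. Cells given erythropoietin (EPO), IL-3/GM-CSF or both together (the combined treatment) gave 3 arrays per treatment, namely the Sca1-low and the Sca1-high fraction at day 3 and cells at day 6, for which the labels name no Sca1 fraction. Sca1, the product of Ly6a, is a surface protein of progenitors. Per the labels, cells in the IL-3/GM-CSF and combined arms received IL-3 and all-trans retinoic acid from the start and GM-CSF only after day 3. Each of the 10 conditions had 1 array here, so there were no replicates. Gene p-values set a mean difference against its unevenness across treatments and populations, and not against replicate error. List p-values compared the members of a list with all other genes at a preset correlation of 0.01. The estimated correlation of haemoglobin genes, for 1, was 0.949. The duplicate samples that the series design mentions were not analysed here.

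The 75th percentile of the signal was 736 intensity units on the untreated array. Among the EPO arrays it was 309 for Sca1-low, 617 for Sca1-high and 478 at day 6. The IL-3/GM-CSF arrays had 637, 623 and 632 in the same order, and the combined arrays 590.4, 687 and 670.4. Of the 14223 genes tested, between 11147 (78.4%, EPO day 6) and 13500 (94.9%, IL-3/GM-CSF Sca1-high) were well above background on a given array. Levels are log2 signals relative to the 75th percentile of each array, and differences are log2 unless a fold is named. Another scaling moved the median difference of all genes by up to 0.22, from 0.18 to -0.04 in EPO Sca1-low minus untreated, and by more than 0.1 in 15 of the 27 differences between single arrays.

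The first question was how the Sca1-low and Sca1-high fractions of day 3 differed. Transcripts of the red cell program were higher in Sca1-low cells under all 3 treatments: the blood group antigen gene Rhd by 6.23 (SE 0.30, adjusted p = 0.0040), the erythroid membrane gene Ermap by 5.48 (SE 0.38, adjusted p = 0.00538) and the haemoglobin gene Hba-a1 by 3.33 (SE 0.34, adjusted p = 0.0106). Some progenitor and granulocyte transcripts were lower. The progenitor surface gene Cd34 differed by -7.01 (SE 0.76, adjusted p = 0.0118), the calcium-binding gene S100a4 by -7.28 (SE 0.51, adjusted p = 0.00546), the granulocyte factor gene Cebpe by -6.46 (SE 0.22, adjusted p = 0.0040) and the myeloperoxidase gene Mpo by -5.83 (SE 0.36, adjusted p = 0.00446). Cebpe was not well above background in EPO Sca1-low cells, so 2 of 3 Sca1-low arrays measured it. These values came from a limma fit of the 6 day 3 arrays, in which 578 genes rose and 989 fell in Sca1-low cells, with 4401 at an unadjusted p under 0.05. With all 10 arrays in the model, limma called 0 genes, 3581 had an unadjusted p under 0.05 and the lowest adjusted p was 0.111; without EPO day 6 the count was 2462, and without EPO Sca1-low 161. A fit with slide as a block gave the 6-array values again, since every pair of fractions shared a slide. Within their slides, Cd34 differed by -9.23 under EPO, -6.20 under IL-3/GM-CSF and -5.61 under the combined treatment.

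The sorting marker itself separated as sorted. Ly6a lay at 3.02 in untreated cells, at -4.25 and 4.76 in the Sca1-low and Sca1-high fractions under EPO, at -3.43 and 2.64 under IL-3/GM-CSF, and at -2.80 and 1.89 under the combined treatment. It was 6.59 lower in Sca1-low cells (SE 0.85, adjusted p = 0.0171 in the 6-array fit), with 2 of 3 Sca1-low arrays well above background, EPO being the exception. Some transcripts were not well above background on the dim side, and their differences are given as lower bounds against the background limit of the array. Against these limits the amino acid transporter gene Slc38a5 was 59.5-fold higher in Sca1-low cells, and the embryonic globin gene Hba-x 36.9-fold higher. Both values may exceed a true lower bound. The limit of IL-3/GM-CSF Sca1-high was -7.50, which left its values of -7.27 and -6.05 as they were. On the other arrays the limit lay between -5.37 and -4.22. The myeloid repressor gene Gfi1 was at least 73.6-fold lower and the platelet chemokine gene Ppbp at least 88.5-fold lower. The neuropeptide gene Tac2 was higher by 5.83 (SE 0.23) and the disulfide isomerase gene Pdia2 by 5.68 (SE 0.26), both with adjusted p = 0.0040.

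The 18 lists hold markers of blood cell types beside response, proliferation and housekeeping genes. Of these lists, 14 passed the threshold in the 6-array fit and 15 with all 10 arrays. In either fit 0 passed with an estimated correlation. In the 6-array fit, 20 of 27 erythroid regulator and membrane genes were called higher in Sca1-low cells and 1 lower, with a median of 3.00 and adjusted p = 2.46e-11 (adjusted p = 0.158 with an estimated correlation). Of 20 haem synthesis and iron genes 16 were called higher, among them Alad (3.40) and Cpox (3.58), with a median of 1.85 and adjusted p = 1.77e-09 (adjusted p = 0.158 with an estimated correlation). Of 8 haemoglobin genes 6 were called higher, with a median of 3.01 and adjusted p = 1.85e-05 (adjusted p = 0.337 with an estimated correlation). Adjusted over the list alone, 23, 17 and 7 members of these lists were called higher. On the opposite side, 14 of 22 monocyte and macrophage genes were called lower and 1 higher, with a median of -3.16 and adjusted p = 3.02e-11 (adjusted p = 0.158 with an estimated correlation). The chemokine gene Ccl9 was lower by 7.10 (SE 0.23) and the integrin gene Itgax by 6.74, the latter with 2 of 3 Sca1-low arrays well above background. Adjusted over the list alone, 16 of the monocyte genes were lower.

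Lower values in Sca1-low cells also appeared in the stem and progenitor list (median -0.95, 7 of 22 called lower and 1 higher, adjusted p = 1.73e-05, adjusted p = 0.337 with an estimated correlation), where the transcription factor genes Erg and Sox4 were lower by 4.85 and 3.50 (Erg well above background on 2 of 3 Sca1-low arrays). The mast cell and basophil list had a median of -1.92 with 6 of 17 called lower (adjusted p = 2.39e-07, adjusted p = 0.315 with an estimated correlation), including the protease gene Cpa3 at -5.41. The protease gene Mcpt8 was well above background on 1 of 3 Sca1-low arrays, with a difference of -5.59 under IL-3/GM-CSF and bounds of -7.99 under EPO and -5.58 in the combined treatment. Of 19 myeloid regulator and receptor genes 9 were called lower (median -1.51, adjusted p = 9.12e-08, adjusted p = 0.158 with an estimated correlation). The neutrophil list had a median of -1.65 with 7 of 29 called lower (adjusted p = 1.42e-06, adjusted p = 0.317 with an estimated correlation). Its median was -3.41 under IL-3/GM-CSF and -2.63 under the combined treatment, but 0.10 under EPO, where the sign changed to -0.09 and -0.03 with the other scalings. The T and NK lymphoid list had a median of -2.09 (6 of 10 called lower, adjusted p = 1.14e-04, adjusted p = 0.158 with an estimated correlation), the interferon response list -1.41 (5 of 14 called lower, adjusted p = 2.41e-05, adjusted p = 0.158 with an estimated correlation) and the retinoic acid response list -1.12 (4 of 12 called lower and 1 higher, adjusted p = 0.00237, adjusted p = 0.315 with an estimated correlation). Shifts also passed for eosinophil genes (-1.29, adjusted p = 0.00281, adjusted p = 0.217 with an estimated correlation), STAT5 and cytokine feedback genes (-0.42, adjusted p = 0.0426, adjusted p = 0.548 with an estimated correlation) and proliferation genes (0.40, adjusted p = 0.00438, adjusted p = 0.536 with an estimated correlation). The STAT5 median was 0.589 under EPO, against -1.595 under IL-3/GM-CSF and -0.383 under the combined treatment. Megakaryocyte and platelet genes passed with all 10 arrays (-0.40, adjusted p = 0.0370, adjusted p = 0.441 with an estimated correlation) but not with 6 (adjusted p = 0.0970). B lymphoid (-0.11) and housekeeping genes (-0.05) did not pass in either fit, nor did stress and p53 genes, whose median of -0.05 and mean of 0.01 had opposite signs.

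Across genes, the fraction difference under IL-3/GM-CSF correlated with that under the combined treatment (r = 0.774, rho = 0.662), and less so with that under EPO (r = 0.526, rho = 0.394). The EPO and combined differences had r = 0.589 and rho = 0.538, and genes are not independent replicates. Of all genes, 54.9% had 1 sign under the 3 treatments, where independent differences centred on 0 would give 25%. The median difference of all genes was above 0 under EPO (0.151), IL-3/GM-CSF (0.0652) and the combined treatment (0.238). Such a shared shift alone can raise the share. At least 2-fold differences in all 3 treatments were found for 385 genes higher and 917 lower in Sca1-low cells, while 128 genes differed at least 2-fold in opposite directions under EPO and IL-3/GM-CSF. Per treatment, 3846 genes differed at least 2-fold under EPO, 3302 under IL-3/GM-CSF and 3379 under the combined treatment. The last count was 1678 higher and 1701 lower, and it became 787 higher and 1400 lower after background correction and quantile normalization.

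**Figure D1:**
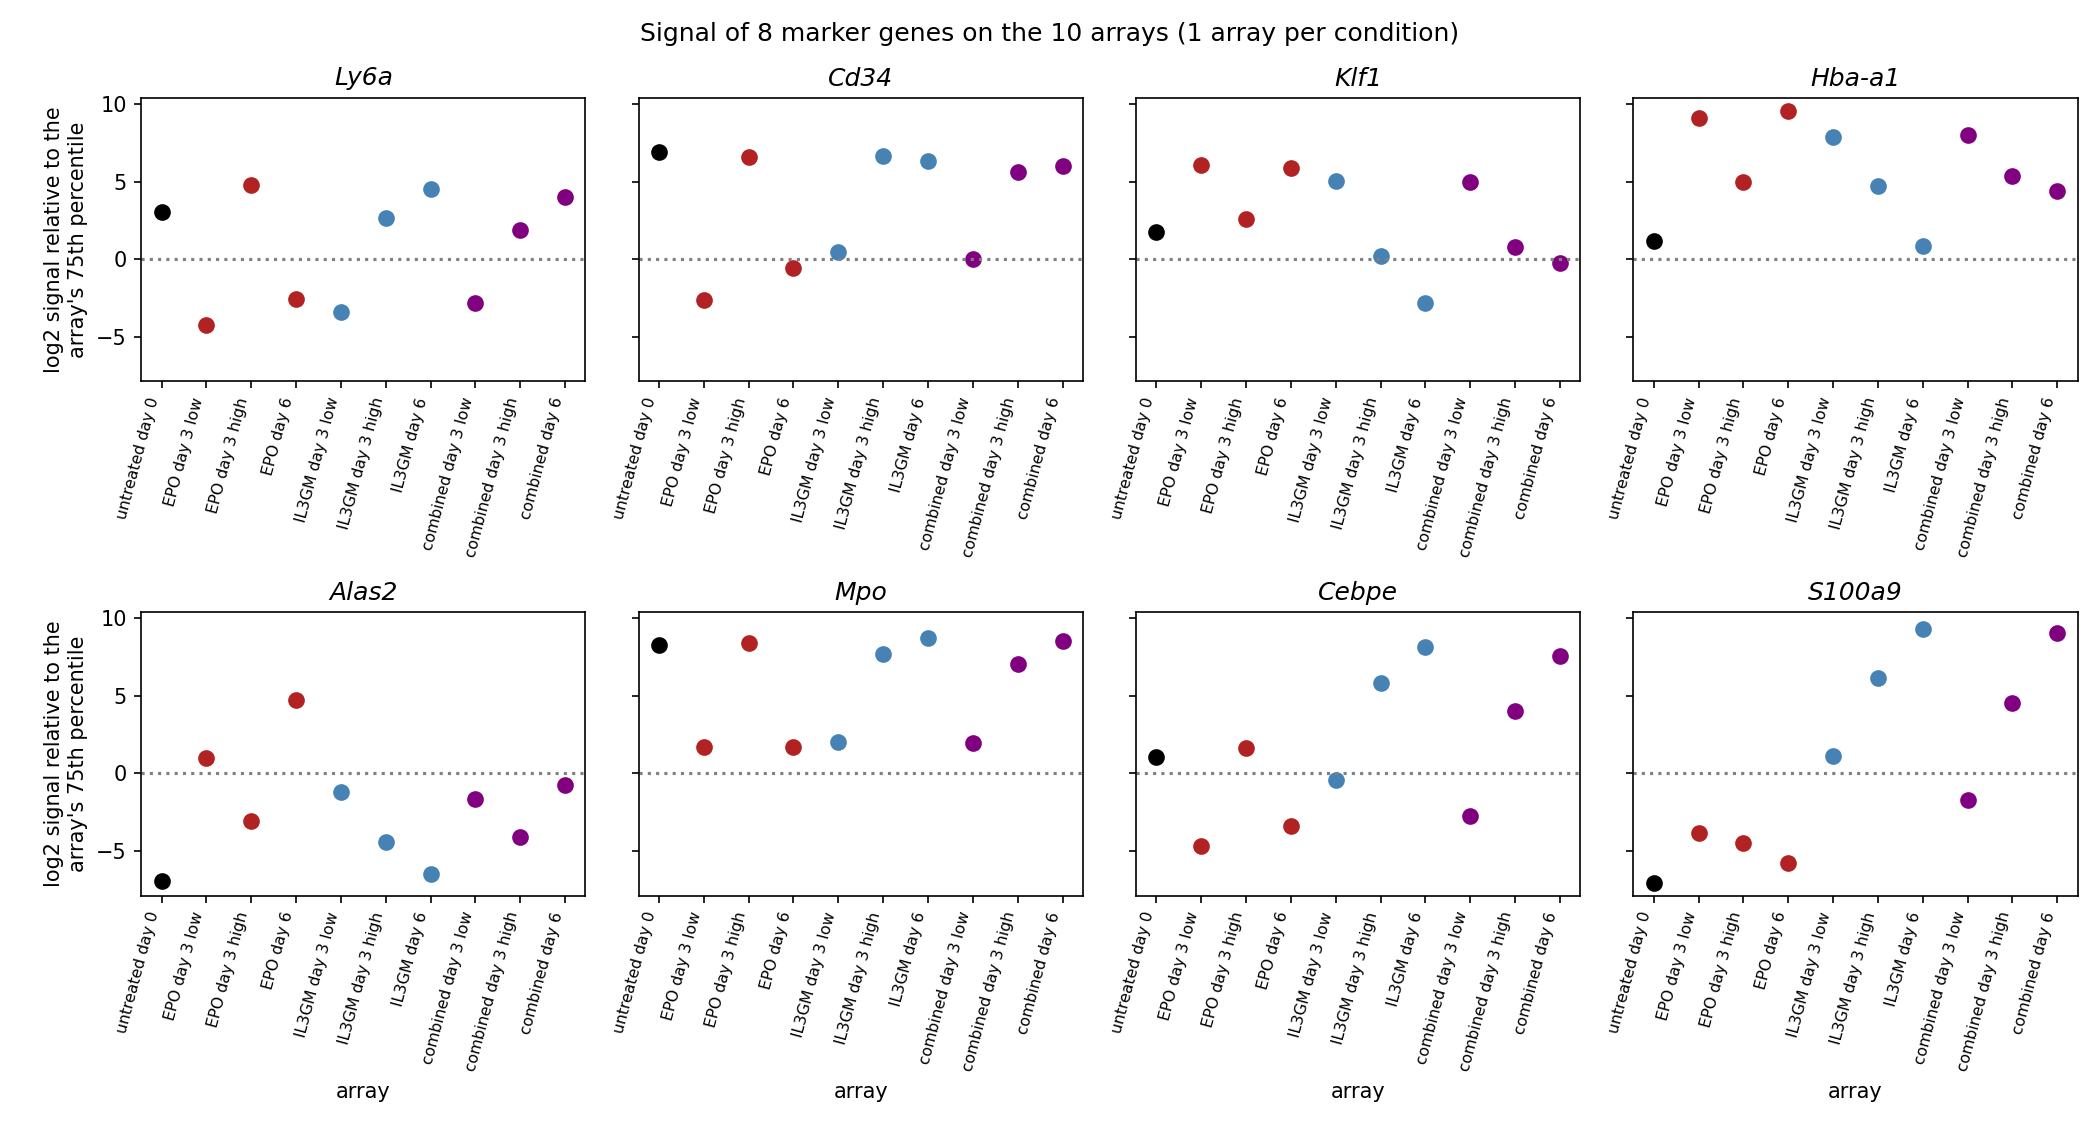
Level of 8 marker genes (log2 signal relative to the 75th percentile of the array, vertical axis) on the 10 arrays (horizontal axis), with 1 point per array, coloured black for untreated, red for EPO, blue for IL-3/GM-CSF and purple for the combined treatment. Klf1 lay at 6.07, 5.05 and 4.99 in the Sca1-low arrays and at 2.60, 0.20 and 0.77 in the Sca1-high arrays of EPO, IL-3/GM-CSF and the combined treatment.

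Each treatment was next compared with untreated cells to see which programs it moved. Under EPO, the haemoglobin gene Hba-a1 was higher by 6.67 on average (SE 2.19) and by 7.89, 3.75 and 8.37 in Sca1-low, Sca1-high and day 6 cells. The haem enzyme gene Alas2 was on average at least 70.3-fold higher, with levels of 0.95, -3.07 and 4.75 in Sca1-low, Sca1-high and day 6 cells. Cd34 was lower by 5.79 (SE 1.94), though by only 0.34 in Sca1-high cells. The cytokine feedback gene Cish was higher by 4.71 (SE 0.82). None of these differences passed for a single gene: limma called 0 genes for EPO, with 1494 at an unadjusted p under 0.05 and a lowest adjusted p of 0.221, and 1 gene without IL-3/GM-CSF day 6. A fit with slide as a block called 1040 genes, and the pair of day 6 and untreated arrays on 1 slide differed by 8.37 in Hba-a1 and -7.48 in Cd34.

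Haemoglobin genes had a median of 4.01 under EPO (adjusted p = 0.00151, adjusted p = 0.490 with an estimated correlation). By sign alone, 8 of 8 were higher in all 3 arrays. Hba-x, however, was not well above background in Sca1-high (-6.72) or untreated cells (-6.90). Erythroid genes had a median of 2.38 (adjusted p = 0.00151, adjusted p = 0.498 with an estimated correlation) and haem genes 1.48 (adjusted p = 7.59e-05, adjusted p = 0.490 with an estimated correlation). The stress and p53 list was higher, with a median of 0.94 and 13 of 16 genes higher in all 3 arrays (adjusted p = 0.00119, adjusted p = 0.333 with an estimated correlation), led by the kinase-like gene Trib3 at 3.25. STAT5 and cytokine feedback genes had a median of 1.80 (adjusted p = 0.0131, adjusted p = 0.490 with an estimated correlation), which became -0.67 with slide as a block (adjusted p = 0.858). That fit passed 12 of the 18 lists, 4 of them anew, with medians of -3.88 for myeloid, -6.86 for neutrophil, -2.36 for T and NK and 0.66 for proliferation genes, and 0 with an estimated correlation (lowest adjusted p = 0.176). The lists that passed in both fits had medians with slide as a block of 11.63 for haemoglobin, 9.01 for erythroid, 4.17 for haem, 0.94 for stress, -2.54 for stem and progenitor, -6.14 for monocyte, -5.06 for mast cell and -3.45 for eosinophil genes, all resting on additivity. Lower medians were found for stem and progenitor (-1.005, adjusted p = 3.44e-05), monocyte (-1.55, adjusted p = 0.00405), mast cell (-1.35, adjusted p = 0.00151) and eosinophil genes (-1.12, adjusted p = 0.0412), each with adjusted p = 0.490 with an estimated correlation. In Sca1-high cells, however, the monocyte, mast cell and eosinophil medians were 0.38, 0.32 and 0.15, the last of which became -0.03 under another scaling. Neutrophil genes had a median of 0.36 but a mean of -0.26, and the median became -0.01 after background correction and quantile normalization. The remaining lists did not pass with all arrays and no block, with medians of -0.44 for myeloid, -0.22 for megakaryocyte, -0.10 for B lymphoid, -1.197 for T and NK, -0.32 for retinoic acid and -0.43 for interferon genes. Proliferation (0.14) and housekeeping genes (0.21) changed sign under other scalings.

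Under IL-3/GM-CSF, the granulocyte genes S100a9 and Stfa1 were higher, and neither was well above background in untreated cells. The calprotectin gene S100a9 lay at -7.06 in untreated cells, at 1.11 and 6.13 in the Sca1-low and Sca1-high fractions and at 9.27 at day 6, and was on average at least 1735-fold higher. The stefin gene Stfa1 was at least 1665-fold higher. Mast cell protease genes were lower, Mcpt2 by 5.26 (SE 1.61) and Mcpt4 by 5.21 (SE 1.48), as was the growth factor receptor gene Kit, by 2.88 (SE 0.75). Cish was higher by 5.56 (SE 0.82). With 0 genes called by limma, 963 had an unadjusted p under 0.05 and the lowest adjusted p was 0.216, and without EPO Sca1-low 7 genes were called. Neutrophil genes had a median of 2.62 with 15 of 29 higher in all 3 arrays (adjusted p = 7.11e-08, adjusted p = 0.497 with an estimated correlation), and STAT5 genes 1.62 with 10 of 15 (adjusted p = 2.88e-08, adjusted p = 0.497 with an estimated correlation). Mast cell genes were lower (-1.99, adjusted p = 1.71e-06), as were stem and progenitor genes (-0.83, adjusted p = 9.72e-05) and megakaryocyte genes (-0.65, adjusted p = 0.0160), each with adjusted p = 0.497 with an estimated correlation. No IL-3/GM-CSF array shared a slide with the untreated array. The neutrophil median became -4.41 with slide as a block (adjusted p = 9.16e-08, adjusted p = 0.290 with an estimated correlation), a value that rests on additivity, and 299 genes were called. The STAT5 median became -0.53 (adjusted p = 0.698), megakaryocyte genes no longer passed (-0.79, adjusted p = 0.354), and the mast cell and stem medians became -7.31 and -2.93.

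The other lists did not pass under IL-3/GM-CSF with all arrays and no block. Erythroid genes had a median of -0.04, which changed sign to 0.18 after background correction and quantile normalization, and haemoglobin genes 1.59. Their values in Sca1-low cells were 1.99 and 4.52, against -2.48 and -1.25 at day 6. Medians were 0.21 for haem, 0.50 for myeloid, 0.24 for monocyte, -0.20 for B lymphoid, -0.87 for T and NK, 0.54 for retinoic acid, -0.25 for interferon and 0.34 for stress genes. Eosinophil genes had a median of 0.01 and a mean of -0.48. Proliferation genes had a median of 0.02 with a test direction of lower, and both they and housekeeping genes (0.12) changed sign under other scalings, as did the eosinophil median. The fit with slide as a block passed 12 of the 18 lists, 9 of them anew, with 0 passing at an estimated correlation (lowest adjusted p = 0.196). Its medians were 7.73 for erythroid, 10.56 for haemoglobin, 3.98 for haem, -4.77 for myeloid, -4.24 for monocyte, -3.22 for eosinophil, -1.80 for B lymphoid, -2.10 for T and NK and 0.55 for proliferation genes, all resting on additivity. The erythroid and haemoglobin medians lie above the 1.99 and 4.52 of Sca1-low cells and the -2.48 and -1.25 of day 6.

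The combined treatment was also compared with untreated cells. S100a9 was on average at least 588-fold higher, with bounds of 873-fold in Sca1-high cells and 20218-fold at day 6. Its level in Sca1-low cells was only -1.73. Cish was higher by 4.86 (SE 0.82). The receptor gene Tlr12 was lower by 5.33 (SE 1.2, well above background on 2 of 3 arrays) and Kit by 2.18 (SE 0.75). Limma called 0 genes, with 677 at an unadjusted p under 0.05 and a lowest adjusted p of 0.118, and 1 gene without IL-3/GM-CSF day 6. Neutrophil genes had a median of 1.91 (adjusted p = 1.46e-06), STAT5 genes 1.01 (adjusted p = 6.51e-07), haemoglobin genes 2.69 with 6 of 8 higher in all 3 arrays (adjusted p = 0.00567), stem and progenitor genes -0.66 and mast cell genes -1.80 (both adjusted p = 5.23e-04), and all of these had adjusted p = 0.605 with an estimated correlation. The neutrophil median became -0.97 with slide as a block (adjusted p = 0.00529), the STAT5 median of 0.86 no longer passed (adjusted p = 0.160), and the haemoglobin, stem and mast cell medians became 7.78, -1.41 and -3.04. That fit passed 11 of the 18 lists, 7 of them anew, with medians of 3.34 for erythroid, 1.85 for haem, -2.02 for myeloid, -1.30 for monocyte, -1.36 for eosinophil, -0.86 for B lymphoid and -0.90 for T and NK genes, and 0 with an estimated correlation (lowest adjusted p = 0.256). All its medians rest on additivity. The neutrophil median was -0.36 in Sca1-low cells. On the slide that held both the untreated and the day 6 array it was 4.54 and the haemoglobin median 1.98. The lists that did not pass without a block had medians of 0.46 for erythroid, 0.09 for haem, 0.31 for myeloid, 0.66 for monocyte, -0.31 for megakaryocyte, -0.12 for B lymphoid, -0.15 for T and NK, 0.46 for retinoic acid, -0.17 for proliferation and -0.35 for interferon genes. Eosinophil genes had a median of -0.32 and a test direction of higher. Housekeeping genes had a median of 0.04 and a mean of -0.02, and they and stress genes (0.02) changed sign under other scalings.

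Counting genes well above background on the higher side, at least 2-fold differences from untreated cells numbered 5159 in EPO Sca1-low, 786 in EPO Sca1-high and 3765 at EPO day 6. IL-3/GM-CSF gave 2633, 2301 and 2773 in the same order, and the combined treatment 3128, 2162 and 2097. The EPO Sca1-low count was 2626 higher and 2533 lower. It became 1330 and 1984 after background correction and quantile normalization, and 1873 and 2836 after quantile normalization alone. Across genes, EPO Sca1-high correlated with untreated cells at r = 0.984.

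**Figure D2:**
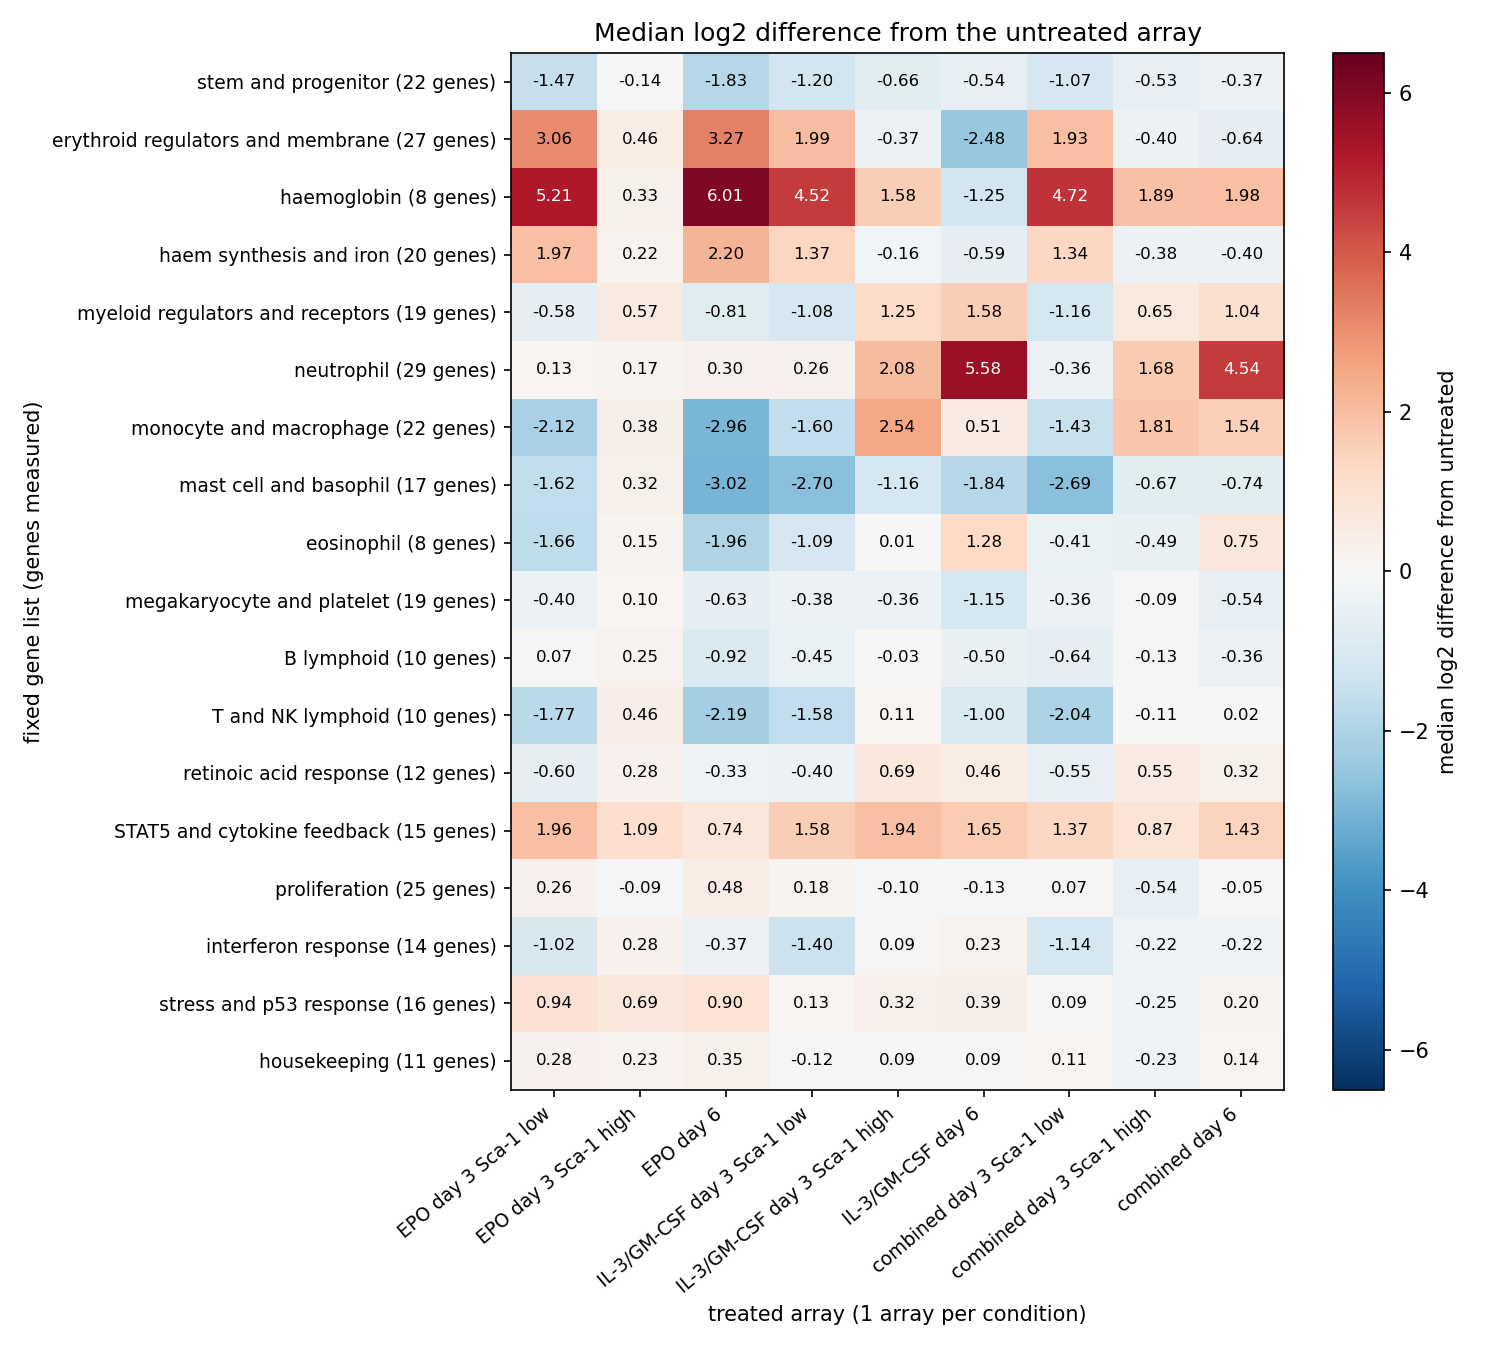
Median log2 difference from untreated cells for 18 fixed gene lists (vertical axis) in the 9 treated arrays (horizontal axis), with the value printed in each cell and the colour scale in log2 units. Erythroid genes had medians of 3.06, 1.99 and 1.93 in the Sca1-low arrays of EPO, IL-3/GM-CSF and the combined treatment, and of 3.27, -2.48 and -0.64 at day 6; several medians near 0, such as those of housekeeping genes, changed sign under other scalings.

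EPO and IL-3/GM-CSF were compared as the treatments that favour red cells and granulocytes. The thromboxane synthase gene Tbxas1, which is expressed in myeloid cells, was lower under EPO by 5.76 (SE 0.36, adjusted p = 0.0347), with -4.96, -6.08 and -6.23 in Sca1-low, Sca1-high and day 6 cells. It was the only gene that passed, and 2684 genes had an unadjusted p under 0.05. With slide as a block, which leaves the day 3 pairs of 1 slide, its difference was -5.52 (adjusted p = 0.180) and limma called 0 genes. Its adjusted p ranged from 0.00225 to 0.582 over the alternatives. Without the EPO Sca1-low array the count rose to 131, and without any single other treated array it fell to 0. S100a9 was well above background on 1 of 3 EPO arrays, Sca1-high, where the difference was -10.65, with bounds of -4.99 in Sca1-low cells and -13.60 at day 6. Cebpe, measured on the same 1 of 3, differed by -4.24 in Sca1-high cells with a bound of -11.56 at day 6. The embryonic globin gene Hbb-bh1 was higher by 5.05 (SE 1.49). The surface antigen gene Ly6d and Alas2 were not well above background at IL-3/GM-CSF day 6. Ly6d was higher by 3.80, 4.41 and at least 7.65 in Sca1-low, Sca1-high and day 6 cells, and Alas2 by 2.16, 1.37 and at least 9.01.

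Neutrophil genes were lower under EPO, with a median of -3.51 (adjusted p = 1.51e-09, adjusted p = 0.612 with an estimated correlation). Lower values in all 3 populations were found for 14 of the 29, and 9 were called when adjusted over the list alone. Their median was -0.32 in Sca1-low, -1.93 in Sca1-high and -7.13 at day 6. With slide as a block it was -1.01 (adjusted p = 8.08e-05, adjusted p = 0.520 with an estimated correlation). Monocyte genes were lower as well (-1.43, adjusted p = 9.70e-05, adjusted p = 0.612 with an estimated correlation), and 6 of 22 were called when adjusted over the list alone. Erythroid genes were higher, with a median of 2.76 (adjusted p = 5.05e-05, adjusted p = 0.648 with an estimated correlation) and of 0.46, 0.99 and 7.13 in the 3 populations. With slide as a block the erythroid median was 0.87 (adjusted p = 5.90e-05, adjusted p = 0.490 with an estimated correlation). Haem genes were higher (1.30, adjusted p = 1.89e-06, adjusted p = 0.612 with an estimated correlation), in all 3 populations for 14 of 20, and 1 was called when adjusted over the list alone. Haemoglobin genes had a median of 2.49 (adjusted p = 0.0120, adjusted p = 0.686 with an estimated correlation) that was 7.66 at day 6 but -0.50 in Sca1-high cells, and 0.55 with slide as a block (adjusted p = 0.430).

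Stress and p53 genes were higher under EPO (0.53, adjusted p = 0.0160, adjusted p = 0.469 with an estimated correlation), and 6 of 16 were called when adjusted over the list alone. Lower medians were found for myeloid (-0.95, adjusted p = 0.00539, adjusted p = 0.686 with an estimated correlation), retinoic acid (-0.68, adjusted p = 0.0101, adjusted p = 0.469 with an estimated correlation), STAT5 (-0.70, adjusted p = 0.00330, adjusted p = 0.612 with an estimated correlation) and eosinophil genes (-0.89, adjusted p = 0.0341, adjusted p = 0.648 with an estimated correlation). In Sca1-low cells the myeloid, eosinophil and STAT5 medians were 0.24, 0.24 and 0.08, each of which changed sign under another scaling, and the eosinophil median was 0.70 in Sca1-high cells. In the fit with slide as a block, myeloid (adjusted p = 0.161) and STAT5 genes (adjusted p = 0.149) no longer passed, the eosinophil median became 0.17 (adjusted p = 0.951), and mast cell genes passed with a median of 1.14 (adjusted p = 0.00129, adjusted p = 0.520 with an estimated correlation). That fit passed 7 of the 18 lists and 0 with an estimated correlation (lowest adjusted p = 0.490). Mast cell (0.92), stem and progenitor (-0.15), B lymphoid (0.31) and proliferation genes (0.25) did not pass with all arrays. Megakaryocyte genes had a median of 0.13 and a mean of -0.13, and T and NK genes 0.01 and -0.14. These medians, interferon (-0.05) and housekeeping (0.10) changed sign under another scaling. At least 2-fold differences numbered 2924 in Sca1-low, 1922 in Sca1-high and 4749 at day 6.

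The combined treatment was compared with each single treatment to ask which of them it resembled. Against EPO, Tbxas1 was higher by 5.48 (SE 0.36, adjusted p = 0.0469), with 4.49, 5.71 and 6.24 in Sca1-low, Sca1-high and day 6 cells, and 3356 genes had an unadjusted p under 0.05. With slide as a block, which leaves the day 6 pair of 1 slide, its difference was 6.24 (adjusted p = 0.0171) and limma called 864 genes. Its adjusted p ranged from 0.00325 to 0.460 over the alternatives. Without the EPO Sca1-low array the count was 101, and without any single other treated array it was 0. S100a9 was higher by at least 2.15 in Sca1-low cells, by 9.03 in Sca1-high cells and by at least 13.38 at day 6, since 1 of 3 EPO arrays was well above background. Ly6d was lower by 4.14, 4.71 and at least 8.41, with 2 of 3 combined arrays well above background. Hbb-bh1 was lower by 5.23 (SE 1.49) and the carbonic anhydrase gene Car1 by 4.42 (SE 1.29).

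Haem genes were lower in the combined treatment than under EPO (-1.38, adjusted p = 2.40e-05, adjusted p = 0.723 with an estimated correlation), in all 3 populations for 16 of 20, and 4 were called when adjusted over the list alone. Stress and p53 genes were lower (-0.78, adjusted p = 0.00443, adjusted p = 0.492 with an estimated correlation), and 8 of 16 were called when adjusted over the list alone. Erythroid (-1.98, adjusted p = 0.0145) and proliferation genes (-0.40, adjusted p = 0.00903) were lower, the latter in all 3 populations for 19 of 25, though their Sca1-low median of -0.38 became 0.02 after quantile normalization. Neutrophil (2.88, adjusted p = 1.61e-06), monocyte (1.80, adjusted p = 3.22e-04), myeloid (0.76, adjusted p = 0.0254), eosinophil (0.56, adjusted p = 0.0254) and retinoic acid genes (0.48, adjusted p = 0.0482) were higher. Each of these 7 lists had adjusted p = 0.723 with an estimated correlation. The higher eosinophil median came from day 6 (2.48), against -0.22 in Sca1-low and -0.28 in Sca1-high cells, and the Sca1-low medians of myeloid and retinoic acid genes were -0.73 and -0.15. With day 3 arrays only, eosinophil (adjusted p = 0.717), myeloid (adjusted p = 0.897), retinoic acid (adjusted p = 0.146) and proliferation genes (adjusted p = 0.108) did not pass, and the call of retinoic acid genes was lost in 11 of 17 alternatives. With slide as a block the neutrophil median was 6.21 (adjusted p = 2.58e-15) and the erythroid median -4.57 (adjusted p = 3.10e-14), the day 6 values, retinoic acid genes no longer passed (adjusted p = 0.0698), and the haem, myeloid, monocyte and eosinophil medians were -2.45, 2.60, 3.77 and 2.48. That fit passed 12 of the 18 lists, 4 of them anew, with medians of 0.87 for stem and progenitor, -4.76 for haemoglobin, 2.28 for mast cell and 2.05 for T and NK genes, and 0 with an estimated correlation (lowest adjusted p = 0.191). The medians that did not pass without a block were -1.31 for haemoglobin, 0.27 for stem and progenitor, 0.40 for megakaryocyte, 0.31 for T and NK, 0.35 for STAT5 and 0.25 for interferon genes. Mast cell genes had a median of -0.09 and a mean of 0.04. B lymphoid (-0.06, with a test direction of higher) and housekeeping genes (-0.16) changed sign under other scalings.

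Against IL-3/GM-CSF, the Ly49 receptor gene Klra4 was higher in the combined treatment by 2.14 in Sca1-high cells and by at least 2.93 at day 6, and was not well above background in either Sca1-low array. The haem enzyme gene Alas2 differed by -0.44 in Sca1-low and 0.32 in Sca1-high cells and was at least 3.47 higher at day 6, where IL-3/GM-CSF was not well above background. Gfi1, also not well above background in either Sca1-low array, differed by -1.78 in Sca1-high cells and -0.75 at day 6. Limma called 0 genes, with 261 at an unadjusted p under 0.05 and a lowest adjusted p of 0.704. Erythroid genes were higher (0.50, adjusted p = 0.00293), with medians of -0.04, 0.28 and 1.25 in Sca1-low, Sca1-high and day 6 cells. Haemoglobin genes were higher (1.00, adjusted p = 0.0211), with 0.19 in Sca1-high cells, 2.71 at day 6 and 0.03 in Sca1-low cells, where the sign changed under other scalings. Mast cell (0.60, adjusted p = 0.00638) and megakaryocyte genes (0.28, adjusted p = 0.0357) were higher, though in Sca1-low cells their medians were -0.19 and -0.15. Neutrophil (-0.80, adjusted p = 0.0412), STAT5 (-0.42, adjusted p = 0.0211) and proliferation genes (-0.17, adjusted p = 0.0145) were lower. By sign alone, 22 of 29 neutrophil genes were lower in all 3 populations. These included Ngp, Mgst1 and Cd177, which were not well above background in either Sca1-low array. Each of the 7 lists had adjusted p = 0.881 with an estimated correlation.

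The directions of several of these lists rested on the day 6 array of IL-3/GM-CSF. Without it the erythroid, haemoglobin and neutrophil medians became -0.39, -0.44 and 0.16, and without the combined day 6 array the mast cell median became -0.22. No matched pair of these treatments shared a slide, and with slide as a block the erythroid, haemoglobin and neutrophil medians were -3.44, -4.29 and 5.09 and that of STAT5 genes 0.39 (adjusted p = 0.405). Megakaryocyte genes no longer passed (0.49, adjusted p = 0.368), and the mast cell and proliferation medians became 3.79 and -0.45. The medians of the slide-block fit rest on additivity. Its erythroid and haemoglobin medians lie below those of every population given above. That fit passed 12 of the 18 lists, 7 of them anew, with medians of 1.52 for stem and progenitor, -2.17 for haem, 2.20 for myeloid, 3.06 for monocyte, 1.85 for eosinophil, 1.29 for B lymphoid and 1.85 for T and NK genes, and 0 with an estimated correlation (lowest adjusted p = 0.177). The lists that did not pass without a block had medians of -0.47 for myeloid, -0.39 for monocyte, 0.18 for B lymphoid, -0.16 for retinoic acid, -0.20 for stress and -0.11 for housekeeping genes. The median was negative but the test direction higher for stem and progenitor (-0.03), haem (-0.06), eosinophil (-0.14) and interferon genes (-0.11). The stem, haem and T and NK medians (0.06) changed sign under other scalings.

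Of the genes at least 2-fold apart between EPO and IL-3/GM-CSF at any brightness, the combined treatment lay closer to IL-3/GM-CSF for 87.2% of 3279 in Sca1-low cells, 74.6% of 2029 in Sca1-high cells and 87.4% of 5117 at day 6. EPO Sca1-low and EPO day 6 were the dimmest arrays. Noise on an EPO array can both select genes and leave the combined array closer to IL-3/GM-CSF, so these shares are not a test of resemblance. Of all 14223 genes, it lay at least 2-fold above both single treatments for 462, 445 and 224 genes and below both for 109, 279 and 32. The counts above asked only that the combined array be well above background. Those below asked it of both single-treatment arrays, so the counts above and below cannot be set against each other. Across genes, combined day 6 correlated with IL-3/GM-CSF day 6 at r = 0.981 and with EPO day 6 at r = 0.895.

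Day 6 was compared with day 3 over the 3 treatments. Day 3 stood for the equal-weight mean of the sorted fractions and day 6 for cells without a named fraction. The comparison therefore cannot separate day from sorting. In the IL-3/GM-CSF and combined arms it also cannot separate day from GM-CSF, which was added only after day 3. The calprotectin gene S100a8 was higher at day 6 by 7.82 under IL-3/GM-CSF and 10.09 under the combined treatment, where 1 of 2 day 3 arrays measured it, and was not well above background on any EPO array. The erythroid factor gene Klf1 was higher by 1.55 under EPO and lower by 5.46 and 3.10 under the other two. Limma called 0 genes, with 1371 at an unadjusted p under 0.05 and a lowest adjusted p of 0.151, and 791 were called without the EPO day 6 array. Neutrophil genes were higher at day 6 (2.72, adjusted p = 1.09e-12, adjusted p = 0.802 with an estimated correlation), with 6 of 29 called when adjusted over the list alone, and with medians of -0.44 under EPO, 4.28 under IL-3/GM-CSF and 4.25 under the combined treatment. Erythroid genes were lower (-1.42, adjusted p = 0.00199, adjusted p = 0.805 with an estimated correlation), with medians of 1.91, -3.64 and -2.10. B lymphoid (-0.66, adjusted p = 0.00963) and megakaryocyte genes (-0.55, adjusted p = 0.0439) were lower, both with adjusted p = 0.802 with an estimated correlation. Myeloid (0.49) and proliferation genes (0.12) were higher, both with adjusted p = 0.0439 and adjusted p = 0.805 with an estimated correlation. The myeloid median was -1.20 under EPO, against 1.61 and 1.65 under the other treatments, the proliferation median -0.13 under IL-3/GM-CSF and the megakaryocyte median 0.04 under the combined treatment. Of 17 alternatives, 10 lost the myeloid call, 8 the megakaryocyte call and 9 the proliferation call, which 1 more reversed.

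No day 6 array shared a slide with a day 3 array of its own treatment. Limma called 657 genes with slide as a block, and the B lymphoid median became 0.99 (adjusted p = 0.429) and the proliferation median -0.27 (adjusted p = 0.174), and megakaryocyte genes no longer passed (-0.29, adjusted p = 0.671). The neutrophil, erythroid and myeloid medians became 11.08, -8.35 and 4.04. All of these lie outside the range of the medians given above for each treatment. They rest on the additivity of the slide-block fit, as do its other medians, and are not read as day differences. That fit passed 10 of the 18 lists, 7 of them anew, with medians of 1.21 for stem and progenitor, -8.60 for haemoglobin, -2.93 for haem, 5.49 for monocyte, 3.45 for mast cell, 2.38 for eosinophil and 1.41 for T and NK genes, and 0 with an estimated correlation (lowest adjusted p = 0.189). The lists that did not pass without a block had medians of -0.95 for haemoglobin, -0.40 for haem, 0.42 for monocyte, -0.36 for mast cell, 0.26 for eosinophil, -0.14 for T and NK, 0.15 for retinoic acid, 0.30 for STAT5 and 0.09 for interferon genes. Stem and progenitor genes had a median of 0.00 and a mean of -0.01, and their sign and that of stress genes (0.03) changed under other scalings, while housekeeping genes lay at 0.00.

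Each array was placed on a line between the day 6 arrays, where 0 stands for IL-3/GM-CSF and 1 for EPO, from the 4749 genes at least 2-fold apart between them and well above background on the higher side. Untreated cells had a median position of 0.348 and EPO Sca1-high cells 0.395. The Sca1-low arrays lay nearer the EPO end, at 0.922 for EPO, 0.711 for IL-3/GM-CSF and 0.724 for the combined treatment. The Sca1-high arrays of IL-3/GM-CSF and the combined treatment lay at 0.202 and 0.173, and combined day 6 cells at 0.135. The ends of the line also differed in the sorting marker. Ly6a lay at -2.57 in EPO day 6, at 4.55 in IL-3/GM-CSF day 6 and at 3.99 in combined day 6 cells. A position on this line therefore cannot separate treatment from Sca1 level. At day 3 the erythroid genes Gata1 and Epor, chosen after their values were seen, lay at 6.21 and 5.01 in Sca1-low cells of the IL-3/GM-CSF arm and at 3.27 and 1.13 in its Sca1-high cells.

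**Figure D3:**
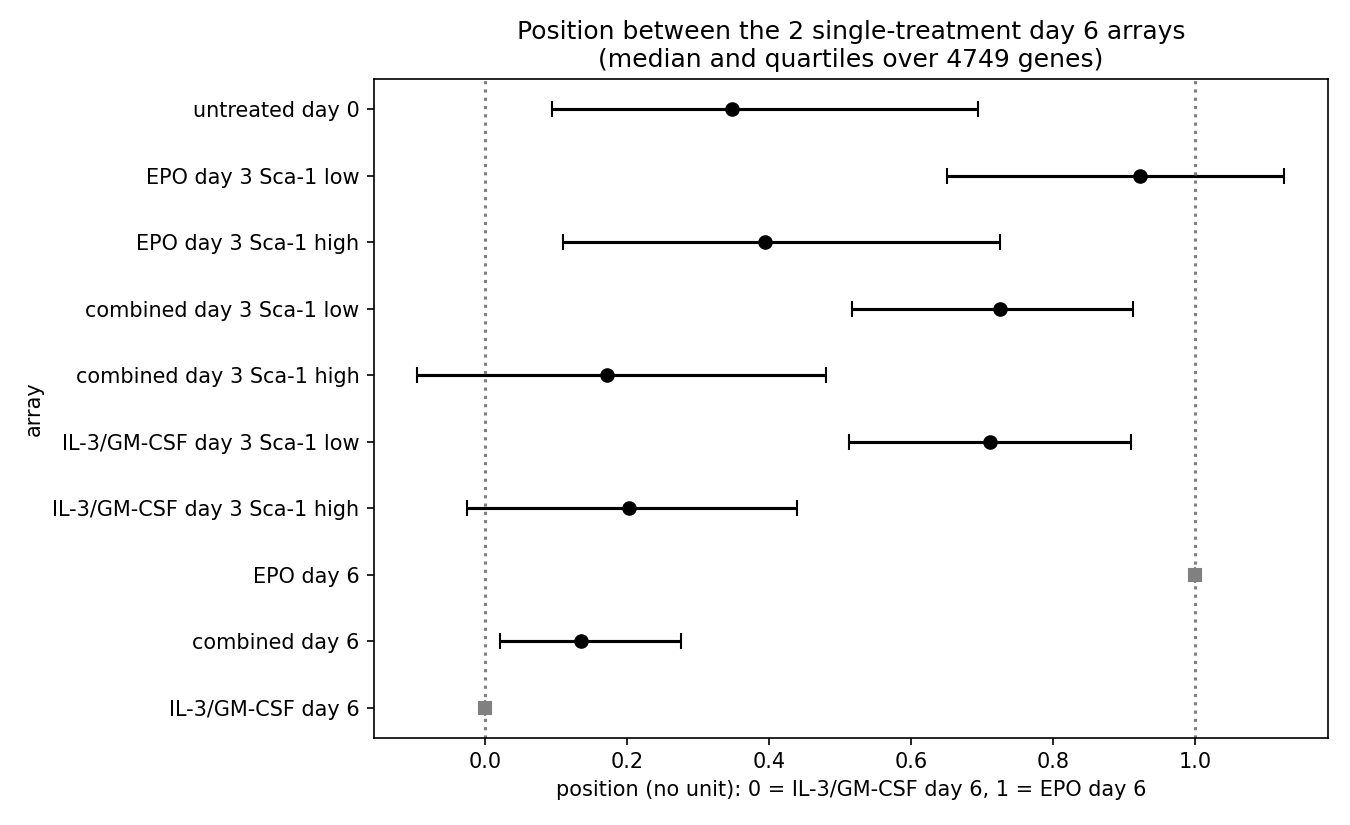
Position of each array (vertical axis labels) between IL-3/GM-CSF day 6 (0) and EPO day 6 (1) on the horizontal axis, without unit; points are medians and lines run from the lower to the upper quartile over 4749 genes. The IL-3/GM-CSF Sca1-low array lies at 0.711 (quartiles 0.512 and 0.909) and its Sca1-high array at 0.202 (quartiles -0.0251 and 0.440).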

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

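The tests of slide, of swapped labels and of mixtures from genes chosen on other arrays, and the comparison of residual spread, were chosen only after the result was seen; the tests of array brightness, of mixtures from genes chosen on the end arrays and of other splits were planned before.

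Several gene lists drew attention because their direction differed between groups of arrays, and none of these differences was tested. Against untreated cells, erythroid genes had a median of 3.27 at EPO day 6 and -2.48 at IL-3/GM-CSF day 6, a difference of 5.75, and haemoglobin genes 6.01 and -1.25, a difference of 7.26. Eosinophil genes had -1.96 and 1.28, a difference of -3.24. Between the Sca1-low and Sca1-high fractions of IL-3/GM-CSF, myeloid genes had -1.08 and 1.25, a difference of -2.33, and monocyte genes -1.60 and 2.54, a difference of -4.13. In the combined treatment monocyte genes had -1.43 and 1.81, a difference of -3.24.

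Probes for genomic regions without a gene name, which entered no gene test, also carried a signal. Relative to untreated cells the mean of the 3 Sca1-low arrays was 4.84 higher for the region on mm9 chromosome 10 from 93975406 to 93977476 and 2.57 higher for the region on chromosome 5 from 77084398 to 77086144. The mean of the 3 Sca1-high arrays was 1.21 higher for the region on chromosome 10 from 83181374 to 83249774, while the mean of its 3 Sca1-low arrays was 3.10 lower. These differences were not tested.

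The Sca1-low array of IL-3/GM-CSF at day 3 lay toward the EPO end of the line between the day 6 arrays. The ends of the line also differed in Ly6a, at -2.57 for EPO and 4.55 for IL-3/GM-CSF. This position is therefore not independent of the sort. A slide effect alone is argued against by the 0.508 between the fractions of IL-3/GM-CSF on 1 slide, swapped labels by the lower of the 2 Sca1-low positions, 0.711, and array brightness by the 0.541 left after quantile normalization. A mixture of cells like EPO Sca1-low and cells like IL-3/GM-CSF Sca1-high would give equal shares from both gene sets, but the EPO-like share was 0.293 from 549 genes and 0.947 from 1134, a difference of -0.654 (95% interval -0.694 to -0.618, and -0.636 and -0.527 under the other normalizations chosen after seeing the data). Choosing genes by the end arrays could pull the 2 shares apart, and with genes chosen on the day 6 arrays instead they were 0.553 and 0.963, a smaller difference of -0.411 (interval -0.466 to -0.359, and -0.317 and -0.253 under the other normalizations). Other mixtures remain open, and these intervals resample genes of 1 array per condition, so the position of 0.711 rests on 1 array.

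The combined treatment at day 6 lay near IL-3/GM-CSF day 6, at 0.135. Its Ly6a level of 3.99 was also nearer the 4.55 of IL-3/GM-CSF day 6 than the -2.57 of EPO day 6. A slide effect is argued against, since combined day 6 shared its slide with EPO day 6 and not with IL-3/GM-CSF day 6. A mixture of cells like the 2 single treatments would also give equal shares, but the EPO-like shares were 0.0411 from 666 genes and 0.318 from 1373, a difference of -0.276 (95% interval -0.292 to -0.255, and -0.240 and -0.257 under the other normalizations). With genes chosen on the EPO Sca1-low and IL-3/GM-CSF Sca1-high arrays they were 0.0218 and 0.192, a smaller difference of -0.170 (interval -0.202 to -0.148, over genes of 1 array per condition), so the choice of genes made part of the gap. Haemoglobin genes higher than under IL-3/GM-CSF by a median of 2.71 may reflect a further kind of cell or a level within each cell, which bulk arrays cannot separate.

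Few genes passed the tests of treatment over all populations. The median residual SD was 0.375 with 10 arrays and 0.293 with the 6 day 3 arrays, a ratio of 1.28. This could mean that treatment effects differ between day 3 and day 6, but the fit with fewer arrays also has fewer residual degrees of freedom. Between EPO and IL-3/GM-CSF, erythroid medians were 0.46, 0.99 and 7.13 in Sca1-low, Sca1-high and day 6 cells, and neutrophil medians -0.32, -1.93 and -7.13. For these lists the treatment difference was larger at day 6, on 1 array per condition. Stress and p53 medians, at 0.85, 0.18 and 0.68, did not grow. How much of the ratio came from such differences and how much from fewer degrees of freedom was not tested.

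Other splits of the arrays gave too few splits for a share under 0.05 in most comparisons. For EPO against IL-3/GM-CSF the real value was 1 and the highest other 0, with 1 of 10 splits reaching it, and the same held for the combined treatment against EPO. For the combined treatment against IL-3/GM-CSF and for the Sca1 fractions over 10 arrays the real value was 0 and the highest other 0, in 10 of 10 splits. For the Sca1 fractions over 6 arrays the real value was 1567 and the highest other 0, in 1 of 10 splits. For day 6 against day 3 the real value of 0 was reached by all 81 splits that could be fitted. Of these, 1 called 356 genes by placing the Sca1-low arrays of IL-3/GM-CSF and the combined treatment with EPO day 6, which points to a structure of the samples. Across genes, the Sca1-low array of IL-3/GM-CSF correlated with EPO day 6 at r = 0.972.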

How the results depend on the processing

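The tests without the 2 dimmest arrays, with only slide 2 and of the lists with slide as a block, with either correlation, and of mixture shares from genes chosen on other arrays, were chosen after seeing the data. No pairing by replicate was possible because every array carries the same replicate number, so the numbers pair nothing. The fractions of day 3 were compared within treatment in every fit, and both fractions of a treatment shared a slide. Where no cause is given, the cause was not tested.

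Of 66 list results that passed, 26 kept direction and side of the threshold under every alternative other than an estimated correlation, and 0 kept it with an estimated correlation. No array position moved by more than 0.1. The combined treatment against IL-3/GM-CSF gave 0 calls throughout.

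Scaling changed the counts. Background correction with quantile normalization gave 2 calls for EPO against IL-3/GM-CSF and 3 for the combined treatment against EPO, in place of 1 and 1. Under it the genes at least 2-fold from untreated cells numbered 3314, 232, 1719, 1288, 2060 and 1221 in the day 3 arrays (Sca1-low and Sca1-high of EPO, IL-3/GM-CSF and the combined treatment) and 1258 at combined day 6. Between fractions they numbered 2444, 2187 and 2187. The offset of 50 shrinks differences of dim genes by construction.

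The filter on dim probes set how many genes were counted. Without a filter 20508 genes were tested and the combined treatment against EPO gave 0 calls. With genes well above background on all 10 arrays 10631 were tested, which gave 25 calls for the combined treatment against EPO and 1 for IL-3/GM-CSF against untreated. The 2-fold counts fell to 223 in EPO Sca1-high, 1400 and 1074 in IL-3/GM-CSF, 1687 and 989 in the combined treatment, and 2464, 1425 and 926 at day 6. Between fractions they were 2465, 1802 and 1910. This filter leaves out a gene that is dim on even 1 array, so it drops strongly changed genes such as S100a9, at -7.06 in untreated and 9.27 in IL-3/GM-CSF day 6 cells. Where 1 side is not well above background, background limits the difference to a lower bound. EPO Sca1-low and EPO day 6 were the dimmest arrays.

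A threshold of 2 on the log2 scale gave 1575, 205, 1008, 814, 1307 and 701 genes in the day 3 arrays and 1389, 1239 and 838 at day 6, and 1284, 1293 and 1183 between fractions, as a stricter threshold must. An intensity trend gave 1 call for the combined treatment against untreated.

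Slide as a block gave 0 calls for EPO against IL-3/GM-CSF, 864 for the combined treatment against EPO, 1567 for the Sca1 fractions, 657 for day 6 against day 3, and 1040, 299 and 63 for EPO, IL-3/GM-CSF and the combined treatment against untreated. It reversed list medians. In the combined treatment against IL-3/GM-CSF erythroid genes became -3.44, haemoglobin genes -4.29, neutrophil genes 5.09 and STAT5 genes 0.39. In day 6 against day 3, B lymphoid genes became 0.99 and proliferation genes -0.27. Against untreated cells STAT5 genes became -0.67 under EPO, and neutrophil genes -4.41 under IL-3/GM-CSF and -0.97 under the combined treatment. By construction this fit uses only pairs within slides and additivity. In the combined treatment against IL-3/GM-CSF no matched pair shared a slide. Its erythroid and haemoglobin medians there lay outside the range of the separate populations.

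Fewer arrays changed the calls as well. Day 3 arrays only gave 0 calls for EPO against IL-3/GM-CSF and for the combined treatment against EPO, and only the groups compared also gave 0 and 0. Only the groups compared gave 1567 for the Sca1 fractions. With only slide 2 these were 0 for EPO against IL-3/GM-CSF and 465 for the Sca1 fractions. Without the 2 dimmest arrays there were 297 for EPO against IL-3/GM-CSF, 195 for the combined treatment against EPO, 2198 for the Sca1 fractions, 1373 for day 6 against day 3, 348 for IL-3/GM-CSF against untreated and 235 for the combined treatment against untreated.

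Leaving out 1 array moved the calls from 0 to 131 for EPO against IL-3/GM-CSF and from 0 to 101 for the combined treatment against EPO, both highest without EPO Sca1-low. The Sca1 fractions ranged from 0 to 2462 and day 6 against day 3 from 0 to 791, both highest without EPO day 6, and without EPO Sca1-low the Sca1 fractions gave 161. Against untreated cells the ranges were 0 to 1 for EPO (without IL-3/GM-CSF day 6), 0 to 7 for IL-3/GM-CSF (without EPO Sca1-low) and 0 to 1 for the combined treatment (without IL-3/GM-CSF day 6). In the combined treatment against IL-3/GM-CSF, the erythroid median ranged from -0.39 to 1.30 and the haemoglobin median from -0.44 to 1.98, both lowest without IL-3/GM-CSF day 6. The neutrophil median ranged from -1.85 to 0.16, highest without that array, and the mast cell median from -0.22 without combined day 6 to 1.11.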

Other observations

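The tests behind this part were planned before the data were examined, except those of slide and labels, which were chosen after the result was seen.

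Combined day 6 cells held globin transcripts beside granulocyte transcripts. The haemoglobin gene Hba-a1 lay at 4.40 against 0.82 at IL-3/GM-CSF day 6 and 9.56 at EPO day 6, and the calprotectin gene S100a9 at 9.05 against 9.27 and -5.80, the last not well above background. The erythroid list had a median of -0.64 against untreated cells, with 3 of 27 genes at least 2-fold higher and 13 lower. The embryonic globin gene Hbb-y was 15.4-fold higher at day 6 in the combined treatment than under IL-3/GM-CSF. The myeloid factor gene Spi1, chosen after its values were seen, lay at 0.40 in combined and 0.56 in IL-3/GM-CSF day 6 cells and at -1.83 in EPO day 6 cells. The mast cell protease gene Mcpt2 lay at 7.16 in untreated cells, at 4.14 in combined day 6 cells and at 1.23 in IL-3/GM-CSF day 6 cells. The transport gene Ift27 was 67.4-fold higher in the combined treatment at day 6 than under IL-3/GM-CSF. This difference was carried by a low value of -1.65 on the IL-3/GM-CSF day 6 array. Ift27 lay at 4.42 in combined day 6 cells, at 4.44 in untreated cells and between 3.91 and 5.01 on the other arrays.

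Under IL-3/GM-CSF the granule genes Ngp and Camp were 444-fold and 372-fold higher at day 6 than in Sca1-high cells of day 3. Day, sorting and the GM-CSF added after day 3 are not separated in these values. Of 3475 regions without a gene name, 32 were at least 2-fold higher and 50 lower in Sca1-low cells under all 3 treatments, or 2.36%, against 9.15% of named genes. The region on mm9 chromosome 10 from 93975406 to 93977476 was higher by 4.64, 5.52 and 4.73 under EPO, IL-3/GM-CSF and the combined treatment. The region on chromosome 1 from 175705225 to 175717250 was lower, at -5.70, -5.22 and -4.00.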
